A study of Arabidopsis thaliana with 14 samples.

How the data were processed

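The deposited files hold raw read counts per gene for each of the 14 libraries, which the submitters' processing notes ascribe to STAR 2.7.7a and the genome TAIR10. The annotation behind the counts is not given in the sources used here. Each file held 34218 genes after 4 lines of reads that fell in no gene, with a column that ignores strand and a column for each strand. The column of the strand that held most reads was used, a choice made from the counts, since the opposite strand held 4.86% to 5.51% of reads. Of the genes, 32548 were in the reference annotation of TAIR10.1, which gave coordinates and symbols, and 1385 had identifiers that did not start with AT. Total reads per library ranged from 20448913 to 26537437 (median 22235115), and reads in genes from 19458893 to 23928793. Unmapped reads made up 1.53% to 3.2% of a library, multimapping reads 0.978% to 4.65%, reads in no feature 1% to 2.71% and ambiguous reads 0.268% to 0.671%. No library was a copy of another, as chi-square per degree of freedom lay from 20.1 to 157 in the 13 pairs within a group and from 56.2 to 416 in the 78 pairs between groups. Near-identical gene copies (among them LHCB1, RBCS, SAUR19 to SAUR24, AOC and other tandem copies) can exchange or lose reads, so their single values are uncertain.

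Groups were taken from the labels as treatment and time, and the series' design text calls the replicates biological. All libraries were fitted together in R 4.3.3 with edgeR 4.0.16, with TMM factors, filterByExpr by group and 1 coefficient per group, so that the group of 2 libraries borrowed its spread from the others. The quasi-likelihood F test gave p-values for 7 comparisons over 20077 genes, adjusted by the Benjamini-Hochberg method with a threshold of 0.05. SE is the size of the log2 fold change divided by the square root of F. Against a group with 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group. The bound takes the other group's level as measured and leaves out that group's own error. With 1 to 3 counts, the ratio is given with its 95% counting interval.

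Before the data were examined, 28 gene lists with 399 members (391 genes, 337 of them tested) were written down. They were gibberellin biosynthesis, inactivation, perception and signalling, direct DELLA-induced targets, the GASA family, expansins, xyloglucan endotransglucosylases, PRE and auxin-response genes, cell division, floral promoters, floral repressors and jasmonate. The others were salicylic acid, wound and touch, abscisic acid with drought and cold, morning clock, evening clock, photosynthesis, anthocyanin, glucosinolate, leaf senescence, trichome regulators, and markers of floral organs, shoot meristem, seed, guard cells, epidermis and vascular tissue. The lists share some genes, and photosynthesis, guard cell, epidermis and vascular genes are all expressed in leaves. The 24 lists with at least 5 tested genes were tested by camera of limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated for each list and by fry.

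The genes to be named were fixed by rule at the same time. They were FT, a set of gibberellin genes in GA3 against mock, and the 8 largest rises and 8 largest falls past the threshold (5 and 5 between GA3 times). Those had to have a symbol, a mean of at least 5 CPM in the higher group and no overlap between libraries of the groups. From each list described, the members with the smallest p were added. Of 9627 genes called in any comparison, 54.5% had no symbol and could not be named by this rule.

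Alternatives were RLE size factors, TMM without organelle genes, DESeq2 1.42.0, limma-voom, no filter (at least 1 count), a filter of 1 CPM in 3 libraries, a fit of the 2 groups alone, replicate number as a block, and each library left out in turn. Leaving out 1 library of the 168 h group left 1, assumed to vary like the other groups. Values without 1 library are given where a call ended, a sign changed, or a count, a fold or the fold behind a list's median moved by over 1.5 times, except folds given as bounds or counting intervals. The share of higher calls under another scaling stands beside a count where it moved by over 10 percentage points. The fit was tested on simulated data with 200 changed genes. Of 2-fold changes it recovered 20% with 3 libraries against 3 and 7% with 2 against 3, and of 4-fold changes 68% and 62%, with 8 of 96 and 6 of 75 calls false. The 6 libraries of each comparison of 3 against 3 were also split in all 10 ways.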

Results

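RNA sequencing measured transcript levels in rosette leaves of ft-10, an Arabidopsis line with a lesion in FT, the gene for the mobile flowering signal. Microneedles made of silk and loaded with the gibberellin GA3 at 15 mM were injected into 30-day-old plants grown in 16 h of light and 8 h of dark at 22 °C. The 14 libraries formed 5 groups. Untreated plants were taken at 0 h (n = 3), plants with GA3 needles at 3 h (n = 3), 24 h (n = 3) and 168 h (n = 2), and plants with needles without GA3 (mock) at 24 h (n = 3). Total reads per library ranged from 20448913 to 26537437, of which 88.8% to 95.8% were counted in genes. Levels are given as mean CPM (scaled counts of a library) ± SD and log2 fold changes as the fitted value ± SE, with the n of these groups throughout. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 20077 genes, and those of gene lists from camera over the 24 lists with at least 5 tested genes. Where camera's preset correlation gave a call, the p with an estimated correlation stands beside it.

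FT (AT1G65480) lies on chromosome 1 of TAIR10.1 at 24331373 to 24333999, on the plus strand. Its reads stood at 4.13 ± 0.654 CPM in untreated leaves, 43.7 ± 6.86 CPM at 3 h of GA3, 14.2 ± 5.8 CPM at 24 h of GA3, 34.2 ± 20.5 CPM at 24 h of mock and 7.35 ± 1.49 CPM at 168 h of GA3. Counts per gene do not show which part of the FT transcript was read, so the values do not speak of an intact transcript. Intervals and floors given with low counts cover counting error only.

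**Figure D1:**
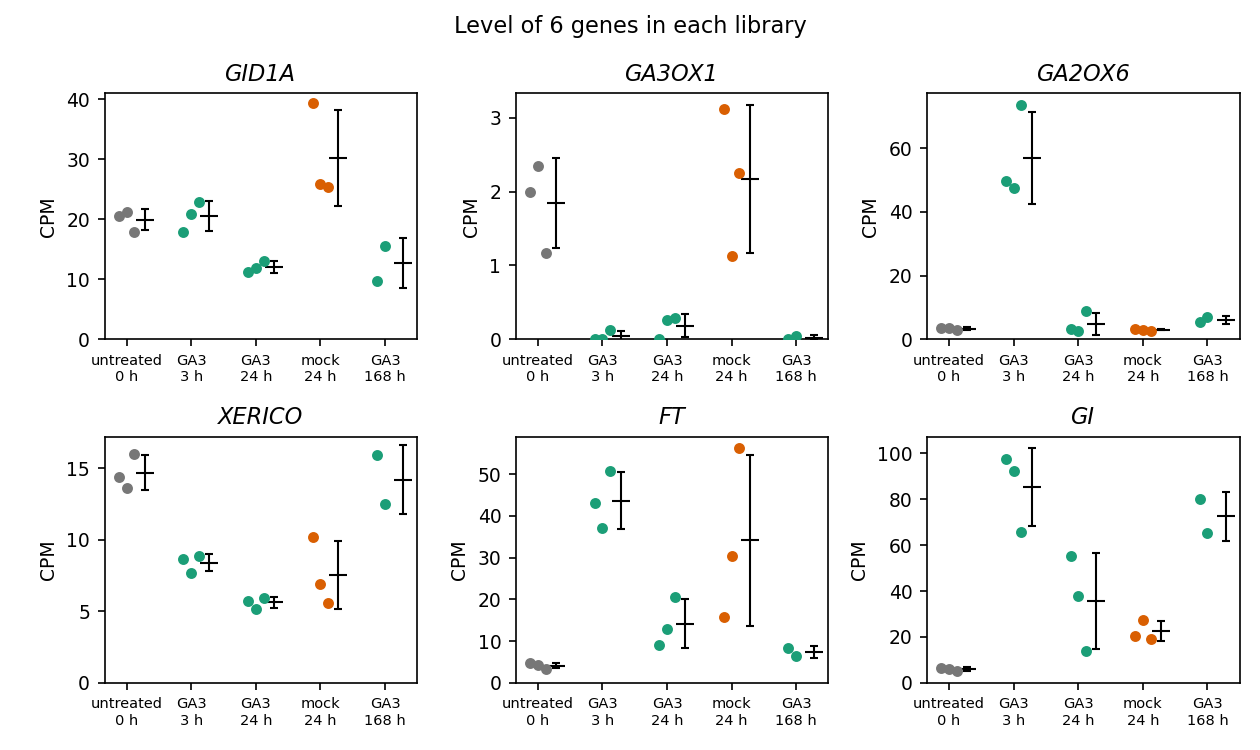
Level in CPM of GID1A, GA3OX1, GA2OX6, XERICO, FT and GI in each library (points, 1 per library), with the mean and SD of each group as a black bar. GID1A lay at 12 CPM on average with GA3 at 24 h and at 30.2 CPM with mock, and GA2OX6 reached 56.8 CPM at 3 h.

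The comparison of GA3 with mock at 24 h asked what GA3 in the needle added to injection of silk alone, and is the only one at matched time. Direct targets that DELLA proteins induce were lower with GA3 as a group, DELLA proteins being the growth repressors that gibberellin removes (median log2 fold change -0.73 over 8 tested genes, camera adjusted p = 5.7e-06, adjusted p = 0.091 with an estimated correlation, range over its alternatives 2.97e-07 to 0.091). Among them the gibberellin receptor gene GID1A (AT3G05120) stood at 12 ± 0.968 CPM with GA3 and 30.2 ± 7.96 CPM with mock (log2 fold change -1.33 ± 0.21, adjusted p = 0.317). GA3OX1 (AT1G15550), whose enzyme makes bioactive gibberellin, stood at 0.183 ± 0.159 against 2.17 ± 0.998 CPM (-3.54 ± 0.93, adjusted p = 0.66, and 0.0185 with DESeq2, range over its alternatives 0.0185 to 0.999; -2.95 without GA3 24 h replicate 1), and the receptor gene GID1B at 2.4 ± 1.14 against 5.19 ± 0.947 CPM (-1.11 ± 0.43). No gene passed edgeR's test after adjustment (0 higher and 0 lower, smallest adjusted p 0.0853), while 1322 genes had an unadjusted p under 0.05. DESeq2 called 19 genes higher and 30 lower, and limma-voom called 0. Within the DELLA list 2 genes were lower when adjusted over the list alone, against 0 over all genes, and DESeq2 called GID1A with adjusted p = 0.000244, in a range over its alternatives of 0.000244 to 0.935. Picked after their values were seen from DESeq2's calls, ARPN, a plantacyanin, had a log2 fold change of -3.23 in DESeq2's fit, the cell wall peroxidase PRX52 -2.11 and the systemic priming gene AZI1 -2.39.

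Genes of gibberellin metabolism with GA3 against mock at 24 h lay in both directions. The synthesis gene GA20OX1 had a log2 fold change of -2.11 ± 0.83 (-2.83 without GA3 24 h replicate 1 and -1.28 without mock replicate 1). GA20OX2 and GA20OX3 were too low to test. With 0 counts in all 3 GA3 libraries, each was at least 2.41-fold lower (floor of 3 counts over the group). This takes their low mock level as measured, so counting error there could lower it. Over the 8 tested synthesis enzymes the median was -0.04 (camera adjusted p = 0.253), and 2 genes were lower when adjusted over the list alone. The 4 tested inactivation enzymes all had fits above 0. They included GA2OX2 (0.86 ± 0.56), GA2OX6 (0.69 ± 0.39) and GA2OX1, which stood at 1.17 ± 0.784 against 0.0359 ± 0.0621 CPM, a ratio with a 95% counting interval of 9.43 to 297. GA2OX6 stood at -0.06 without GA3 24 h replicate 3. GA2OX1 alone was higher when adjusted over the list alone. The DELLA targets XERICO (-0.42 ± 0.21) and SCL3 (-0.78 ± 0.59) and the gibberellin-responsive GASA4 (0.78 ± 0.5) and GASA6 (-0.01 ± 0.73) did not pass, nor did the flowering integrator SOC1 (0.26 ± 0.23) or FT (-1.27 ± 0.4). GASA6 changed sign under 9 alternatives, between 0.01 and 0.29, among them without GA3 24 h replicate 1 (0.26), mock replicate 2 (0.25) and mock replicate 3 (0.29). GA2OX8 and LFY, the floral meristem regulator, were too low to test, LFY with 0 counts in both groups. SPL4, a promoter of the floral transition, stood at 0.99 CPM with GA3 and 7.42 CPM with mock (-2.9 ± 0.48, adjusted p = 0.317, and 2.98e-05 with DESeq2, range over its alternatives 2.98e-05 to 0.935), and was the only one of 14 floral promoters lower when adjusted over the list alone (median 0.38, camera adjusted p = 0.886).

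Other lists placed GA3 above or below mock at 24 h with few or no single genes behind them. The abscisic acid, drought and cold list had a median of 0.49 over 16 genes (camera adjusted p = 0.00267, adjusted p = 0.592 with an estimated correlation), with RD29A, a stress-induced gene, at 0.77 ± 0.39. Photosynthesis genes had a median of 0.34 over 22 (3.15e-05, adjusted p = 0.592 with an estimated correlation), with the Rubisco small subunit RBCS3B at 0.69 ± 0.27. Without GA3 24 h replicate 3 that list's adjusted p was 0.0568. Senescence genes had a median of -0.59 over 13 (0.0406, adjusted p = 0.638 with an estimated correlation), with the regulator NAP at -0.89 ± 0.31, and morning clock genes a median of 0.37 over 8 (0.0274, adjusted p = 0.592 with an estimated correlation), with LNK1 at 0.65 ± 0.23. The senescence call ended without GA3 24 h replicate 2 (adjusted p = 0.19) and mock replicate 1 (0.143), and the morning clock call without GA3 24 h replicate 1 (0.338), replicate 2 (0.058) and mock replicate 3 (0.141). Epidermis markers had a median of 0.32 (0.0429) and vascular markers of 0.39 (0.0406), both with adjusted p = 0.592 with an estimated correlation. The epidermis call ended without GA3 24 h replicate 2 (0.0796), replicate 3 (0.0973), mock replicate 1 (0.175) and mock replicate 3 (0.187), and the vascular call without GA3 24 h replicate 2 (0.0796), replicate 3 (0.427) and mock replicate 2 (0.409). In none of these 6 lists did a gene pass over all genes, and adjusted over the list alone 1 epidermis gene was higher. Growth lists did not pass, among them expansins (median 0.25, camera adjusted p = 0.0632), cell division genes (0.29, 0.0632), and growth-promoting PRE and auxin-response genes (0.36, 0.0632).

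The comparison of mock at 24 h with untreated leaves at 0 h showed what injection of an empty needle and 24 h of time changed together. The cell wall peroxidase PRX52 rose from 1.36 ± 0.533 to 111 ± 61.8 CPM (log2 fold change 6.35 ± 0.66, adjusted p = 0.00367), and the amino acid permease AAP3 from 0.549 ± 0.2 to 16.3 ± 11.9 CPM (4.86 ± 0.57). The lipid transfer proteins EARLI1 (4.72 ± 0.7) and AZI1 (4.52 ± 0.72), the transporter ABCG37 (6.22 ± 0.92), the glutathione transferase GSTU11 (5.11 ± 0.83) and the sulfur-deficiency gene ATSDI1 (4.54 ± 0.8) rose as well. PAP1, the anthocyanin regulator, stood at 5.65 ± 7.59 against 0.0443 ± 0.0443 CPM, a ratio with a 95% counting interval of 39 to 560. That interval leaves out the spread between libraries. PAP1 lost its call without untreated 0 h replicate 1 (adjusted p = 0.0642), replicate 2 (0.134) and replicate 3 (0.187). Among genes that fell were the bHLH growth repressor AIF1 (-3.07 ± 0.41), the invertase inhibitor C/VIF2 (-1.75 ± 0.27), KUF1 (-1.64 ± 0.26), OFP13 (-1.6 ± 0.31), the ion channel CNGC10 (-1.37 ± 0.28), SFH3 (-1.32 ± 0.25), BRH1 (-1.27 ± 0.24) and the cell cycle regulator E2F1 (-1.16 ± 0.22). Epidermis markers were lower as a group (median -1.06 over 7, camera adjusted p = 3.24e-07, 0.03 with an estimated correlation). Of them ATML1, which specifies epidermal identity, fell by 1.13 ± 0.18, 1 gene passed over all genes and 6 adjusted over the list alone. FT (3.05 ± 0.43) and the clock gene GI (1.92 ± 0.39) rose among 14 floral promoters, where 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.557). In all, 122 genes were higher and 34 lower (78.2% higher, and 90.1% with total counts alone as library size). DESeq2 called several times more genes and limma-voom several times fewer, as given in the section on processing. With 1 library left out the counts were 179 and 54 without untreated 0 h replicate 1, 4 and 0 without untreated 0 h replicate 2, 11 and 1 without untreated 0 h replicate 3, 65 and 6 without mock 24 h replicate 1, 69 and 11 without mock 24 h replicate 2 and 51 and 3 without mock 24 h replicate 3. Of the called genes named here, 7 lost the call without untreated 0 h replicate 1 (adjusted p up to 0.0719), 18 lost the call without untreated 0 h replicate 2 (adjusted p up to 0.138) and 17 lost the call without untreated 0 h replicate 3 (adjusted p up to 0.213). The numbers were 8 without mock 24 h replicate 1 (adjusted p up to 0.16), 8 without mock 24 h replicate 2 (adjusted p up to 0.113) and 9 without mock 24 h replicate 3 (adjusted p up to 0.156). Among these, ATSDI1 stood at 3.82 without mock 24 h replicate 1 and GSTU11 stood at 4.41 without mock 24 h replicate 3. PRX52 kept its call without each library in turn. ABCG37 moved to 6.84 and AZI1 to 5.29 without untreated 0 h replicate 1, with the call kept. ABCG37 moved to 5.55, AAP3 to 4.09, EARLI1 to 3.86 and AZI1 to 3.42 without mock 24 h replicate 3, with the call kept.

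Glucosinolate synthesis genes were higher as a group in mock at 24 h than at 0 h (median 0.78 over 14, camera adjusted p = 1.08e-05, adjusted p = 0.784 with an estimated correlation). Of them 0 passed over all genes in edgeR's test and 7 were higher adjusted over the list alone, among them the regulator MYB29 (1.33 ± 0.33) and CYP79F1 (1.74 ± 0.44). The same estimated p of 0.784 belonged to photosynthesis (median -0.43, camera adjusted p = 8.69e-05), jasmonate synthesis and response (1.03, 0.000312), wound, touch and pattern-triggered genes (0.32, 0.0265) and the abscisic acid, drought and cold list (0.64, 0.0303). In the wound list the camalexin gene CYP71A12 rose (2.83 ± 0.55), 1 gene over all genes and 2 adjusted over the list alone, while in the jasmonate list JAZ3 (1.33 ± 0.35) and LOX3 (2.29 ± 0.77, and 1.06 without mock replicate 1) did not pass. The jasmonate call ended without untreated replicate 1 (adjusted p = 0.0682) and mock replicate 1 (0.618, median 0.09), and the wound call without untreated replicate 1 (0.0846). That of the abscisic acid list ended without untreated replicate 2 (0.105), replicate 3 (0.0824) and mock replicate 1 (0.362). CYP71A12 lost its call without each of the 6 libraries in turn, with adjusted p up to 0.181 and a log2 fold change of 2.19 without mock replicate 3. DELLA targets had a median of -0.09 (camera adjusted p = 0.702), with 1 gene higher and 2 lower adjusted over the list alone.

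The comparison of GA3 at 3 h with untreated leaves combined needle, GA3 and 3 h of time. Genes of the abscisic acid, drought and cold response rose, 13 of 16 over all genes and 14 adjusted over the list alone (median log2 fold change 3.62, camera adjusted p = 1.02e-14, adjusted p = 0.172 with an estimated correlation). RD29A went from 31.5 to 2120 CPM (6.08 ± 0.49, adjusted p = 4.53e-05), KIN1 from 1.82 to 65 CPM (5.16 ± 0.57), COR15A from 48.1 to 608 CPM (3.66 ± 0.52) and KIN2 from 66.2 to 994 CPM (3.91 ± 0.57), all 4 known as cold- and drought-induced. The list's median was 1.97 without GA3 3 h replicate 3. All 4 tested gibberellin inactivation enzymes rose, also adjusted over the list alone: GA2OX6 (AT1G02400) from 3.34 ± 0.467 to 56.8 ± 14.5 CPM (4.08 ± 0.42, adjusted p = 0.000217), GAMT2 (4.9 ± 1.15), GA2OX2 (2.39 ± 0.58) and GA2OX1 (4.31 ± 1.16). The synthesis gene GA3OX1 fell from 1.84 ± 0.608 to 0.0411 ± 0.0711 CPM, a ratio with a 95% counting interval of 14.1 to 208, and was the 1 gene of 8 in its list that passed, also adjusted over the list alone (camera adjusted p = 0.387). Of 8 DELLA targets 3 fell over all genes and 4 adjusted over the list alone, namely GA3OX1, XERICO (-0.8 ± 0.21), BHLH154 (-1.48 ± 0.45) and SCL3 (-1.56 ± 0.6, and -0.5 without untreated replicate 1), the last by the second count (median -0.99, camera adjusted p = 0.0204, adjusted p = 0.426 with an estimated correlation). That call ended without untreated replicate 1 (adjusted p = 0.139) and GA3 3 h replicate 1 (0.0686). Evening clock genes rose, 5 of 8 over all genes and 6 adjusted over the list alone (median 2.64, 1.51e-06, adjusted p = 0.0627 with an estimated correlation): GI (3.85 ± 0.42), GRP7 (2.1 ± 0.29), PRR5 (3.19 ± 0.65) and FKF1, at 3.16 CPM against 0 counts, at least 68.6-fold higher. In all, 1716 genes were higher and 1132 lower (60.3% higher, and 72.1% with total counts alone as library size). With 1 library left out the counts were 920 and 704 without untreated 0 h replicate 2, 910 and 571 without untreated 0 h replicate 3 and 979 and 496 without GA3 3 h replicate 2. BHLH154 lost its call without untreated 0 h replicate 1 (adjusted p = 0.118). GA2OX1, GA2OX2, XERICO and BHLH154 lost their calls without untreated 0 h replicate 2 (adjusted p up to 0.0916). GA2OX1, GA2OX2, XERICO, GAMT2 and BHLH154 lost their calls without untreated 0 h replicate 3 (adjusted p up to 0.0856). GA2OX1 (then at 3.29), XERICO and BHLH154 lost their calls without GA3 3 h replicate 1 (adjusted p up to 0.128). GA2OX1, GA2OX2, XERICO, GAMT2 and BHLH154 lost their calls without GA3 3 h replicate 2 (adjusted p up to 0.139). GA2OX1 moved to 4.91, GAMT2 to 4.31, RD29A to 6.75 and KIN2 to 4.61 without untreated 0 h replicate 1, with the call kept. GAMT2 moved to 8.42 without untreated 0 h replicate 2, with the call kept. PRR5 moved to 4.04 without untreated 0 h replicate 3, with the call kept. KIN1 moved to 4.52 without GA3 3 h replicate 3, with the call kept.

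Among the largest changes at 3 h of GA3 against untreated leaves, PROPEP3, which encodes a danger peptide precursor, stood at 8.85 ± 5.26 CPM against 0 counts, at least 183-fold higher. The jasmonate-inactivating CYP94B1 (8.22 ± 1.56), the transcription factor RAP2.6 (7.86 ± 1.5), DIP2 (7.39 ± 1.3) and PRN (6.86 ± 0.93) rose, and the abscisic acid receptor gene PYL6 (-4.99 ± 0.89), AGP16 (-3.6 ± 0.49) and BXL2 (-3.51 ± 0.61) fell. Jasmonate genes rose, 7 of 27 over all genes and 12 adjusted over the list alone (median 1.64, camera adjusted p = 1.28e-07, adjusted p = 0.592 with an estimated correlation), with JAR1 (2.65 ± 0.24), AOC3 (3.67 ± 0.44) and LOX3 (4.05 ± 0.83). Of 25 wound, touch and pattern-triggered genes 5 rose over all genes, among them FRK1 (4.19 ± 0.82), and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.387). Epidermis markers were lower, 2 of 7 over all genes and 5 adjusted over the list alone with 1 higher (median -0.96, 0.0198, adjusted p = 0.426 with an estimated correlation), with ATML1 at -1.36 ± 0.18. Photosynthesis genes had a median of -0.62 over 22 (4.7e-05, adjusted p = 0.827 with an estimated correlation), where LHCB4.2 fell by 1.22 ± 0.28 as the 1 gene to pass over all genes, and adjusted over the list alone. Floral promoters went both ways, 3 higher and 4 lower of 14, the same counts adjusted over the list alone (camera adjusted p = 0.686), with FT (3.4 ± 0.43) higher and SPL4 (-3.23 ± 0.48) lower. The floral repressor SNZ rose (2 ± 0.42), the 1 of 13 in its list by both counts (0.598). Xyloglucan endotransglucosylases included 2 higher and 3 lower of 22, and 2 and 4 adjusted over the list alone (0.0621), with XTH7 at -1.52 ± 0.21, and 2 of 18 expansins rose by both counts, among them EXPA3 (2.99 ± 0.56, camera adjusted p = 0.715). Of the salicylic acid and systemic resistance list, 1 of 18 fell over all genes, SAG101 (-1.04 ± 0.31), and 0 adjusted over the list alone (0.944). SAG101 lost its call without untreated 0 h replicate 1 (adjusted p = 0.116). SAG101 and LHCB4.2 lost their calls without untreated 0 h replicate 3 (adjusted p up to 0.0566). SAG101 lost its call without GA3 3 h replicate 1 (adjusted p = 0.113). SAG101 and LHCB4.2 lost their calls without GA3 3 h replicate 2 (adjusted p up to 0.115). DIP2 moved to 8.44 and FRK1 to 5.53 without untreated 0 h replicate 1, with the call kept. CYP94B1 moved to 9.01, RAP2.6 to 8.84 and PRN to 8.24 without untreated 0 h replicate 3, with the call kept. PYL6 moved to -6.02 without GA3 3 h replicate 3, with the call kept. Without untreated 0 h replicate 3 the jasmonate list's median was 2.29.

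The comparison of GA3 at 24 h with untreated leaves is the time course's counterpart of the mock comparison. The abscisic acid regulated XERICO, also a DELLA target, fell from 14.7 ± 1.22 to 5.62 ± 0.387 CPM (log2 fold change -1.38 ± 0.21, adjusted p = 0.0109), and the receptor gene GID1B from 12 ± 4.11 to 2.4 ± 1.14 CPM (-2.32 ± 0.44). With GA3OX1 (-3.3 ± 0.92, and -2.71 without GA3 24 h replicate 1) and GID1A (-0.72 ± 0.21), which did not pass over all genes, they made up 4 of 8 DELLA targets lower adjusted over the list alone, where 1 was higher (median -0.97, camera adjusted p = 0.00104, adjusted p = 0.283 with an estimated correlation). Against mock at 24 h the fits of XERICO (-0.42) and GID1B (-1.11) were smaller in size, so mock too was fitted below untreated leaves for them. Of the 8 DELLA targets 0 passed over all genes in mock against untreated leaves, and the difference between the effects was not tested. The fits of GA3OX1 (-3.54) and GID1A (-1.33) against mock were larger in size, since mock was fitted above untreated leaves for both. None of these genes passed edgeR's test against mock. Glucosinolate synthesis genes rose, 5 of 14 over all genes and 8 adjusted over the list alone (median 1.15, 1.79e-06, adjusted p = 0.358 with an estimated correlation), with MYB29 (1.79 ± 0.33), SUR1 (1.17 ± 0.22), FMOGS-OX1 (1.86 ± 0.37) and CYP79F1 (1.9 ± 0.44). The sulfur-deficiency genes ATSDI1 (4.83 ± 0.82), LSU1 (4.67 ± 0.89) and LSU2 (4.11 ± 0.65), PRX52 (4.23 ± 0.61), the galactinol synthase GolS2 (4.27 ± 0.84), the ammonium transporter AMT1;2 (4.26 ± 0.81), NIG1 (4.84 ± 1.19) and TBL26 (4.74 ± 0.99) were among the largest rises. PYL6 (-4.29 ± 0.86), UBC17 (-3.44 ± 0.76), ABCB21 (-3.21 ± 0.75), SPL4 (-3.11 ± 0.48), the anion channel SLAH2 (-2.97 ± 0.62) and SOS3 (-2.95 ± 0.69) were among the largest falls. In all, 587 genes were higher and 402 lower. DESeq2 called 1464 and 1003 and limma-voom 453 and 368, while edgeR's fit of only these 2 groups called 0 and 0 (smallest adjusted p 0.0511, with 4108 genes at an unadjusted p under 0.05). With mock against the same untreated leaves, 88 genes were higher in both and 29 lower in both, against 3.57 and 0.681 for independent calls, and 0 were opposite. Simulated unchanged groups that share a control also gave 0 in both, but they hold no changed gene, so this 0 cannot gauge the shared control. Log2 fold changes of all genes correlated at 0.75, with 78% of the same sign. In those simulated groups the shared control alone gave 0.496 and 66.7%. The control libraries were shared and could not be divided between the comparisons. With 1 library left out the counts were 187 and 136 without untreated 0 h replicate 2, 6 and 0 without untreated 0 h replicate 3, 188 and 105 without GA3 24 h replicate 1 and 140 and 60 without GA3 24 h replicate 2. Of the 27 called genes named in this comparison, here and in the next paragraph, 0 kept the call without each library in turn. Of the 20 named here, 1 lost the call without untreated 0 h replicate 1 (adjusted p up to 0.0657). Without untreated 0 h replicate 2 it was 7 (adjusted p up to 0.103), and without untreated 0 h replicate 3 all 20 (adjusted p up to 0.155). The numbers were 13 without GA3 24 h replicate 1 (adjusted p up to 0.107), 13 without GA3 24 h replicate 2 (adjusted p up to 0.0904) and 3 without GA3 24 h replicate 3 (adjusted p up to 0.0708). Among these, NIG1 stood at 4.08 without GA3 24 h replicate 1, GolS2 stood at 3.06 without GA3 24 h replicate 1, AMT1;2 stood at 3.46 without GA3 24 h replicate 1 and UBC17 stood at -4.08 without GA3 24 h replicate 2. LSU2 moved to 4.74 without untreated 0 h replicate 1, with the call kept. ATSDI1 moved to 4.08 without GA3 24 h replicate 2, with the call kept.

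Further lists differed between GA3 at 24 h and untreated leaves. Gibberellin perception and signalling genes were lower, 3 of 13 over all genes and 5 adjusted over the list alone (median -0.43, camera adjusted p = 0.048, adjusted p = 0.283 with an estimated correlation), with IDD2 at -2.4 ± 0.46. Epidermis markers were lower as well, 2 of 7 and 4 adjusted over the list alone (-0.85, 0.00358, adjusted p = 0.283 with an estimated correlation), with the wax gene KCS6 at -1.58 ± 0.31. The abscisic acid, drought and cold list had 2 genes higher of 16 and 7 adjusted over the list alone (1.23, 0.000123, adjusted p = 0.513 with an estimated correlation), with HAI2 (3.65 ± 0.81) and ABF3 (1.21 ± 0.3). Morning clock genes had 2 higher of 8, and 5 higher and 1 lower adjusted over the list alone (0.98, 0.00788, adjusted p = 0.581 with an estimated correlation), with LNK1 at 1.55 ± 0.24. Jasmonate genes had 1 of 27 higher by both counts, JAR1 (0.97 ± 0.23), with a median of 0.84 (0.00358, adjusted p = 0.768 with an estimated correlation), and salicylic acid genes 1 of 18 by both counts, WRKY62 (3.84 ± 0.93), with a median of 0.75 (0.0154, adjusted p = 0.768 with an estimated correlation). The wound, touch and pattern-triggered list had 0 of 25 by both counts in edgeR's test and a median of 1.11, or 0.82 with 1 gene at its bound (0.0125, adjusted p = 0.581 with an estimated correlation). Calls of lists that ended with 1 library left out were those of perception and signalling without untreated replicate 1 (adjusted p = 0.0669), untreated replicate 2 (0.0526), GA3 24 h replicate 2 (0.221) and replicate 3 (0.0856), and of jasmonate (0.114), wound (0.0602) and morning clock (0.0669) without untreated replicate 1. The wound call also ended without GA3 24 h replicate 2 (0.388, median 0.07), and the salicylic acid call without untreated replicate 2 (0.212), untreated replicate 3 (0.0836) and GA3 24 h replicate 1 (0.164, median 0.13). JAR1, WRKY62 (then at 3.25), HAI2, ABF3 and KCS6 lost their calls without untreated 0 h replicate 2 (adjusted p up to 0.113). IDD2, JAR1, WRKY62, HAI2, ABF3, LNK1 and KCS6 lost their calls without untreated 0 h replicate 3 (adjusted p up to 0.17). IDD2, JAR1, WRKY62 (then at 2.96), HAI2, ABF3 and KCS6 lost their calls without GA3 24 h replicate 1 (adjusted p up to 0.135). IDD2, JAR1, WRKY62, ABF3 and KCS6 lost their calls without GA3 24 h replicate 2 (adjusted p up to 0.0957). WRKY62 moved to 5.04 and HAI2 to 4.56 without untreated 0 h replicate 1, with the call kept. Without untreated 0 h replicate 1 the salicylic acid list's median was 2.34.

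The comparison of GA3 at 168 h (n = 2) with untreated leaves at 0 h spans a week of plant age as well as needle and GA3. Time of day may differ too, since harvest times are not in the labels. All 22 photosynthesis genes fell, over all genes and adjusted over the list alone (median log2 fold change -1.79, camera adjusted p = 1.1e-14, adjusted p = 0.261 with an estimated correlation). RBCS3B fell from 6160 to 780 CPM (-2.98 ± 0.35, adjusted p = 0.00049), RBCS2B from 4080 to 257 CPM (-3.99 ± 0.51) and the light-harvesting gene LHCB1.3 from 15800 to 2400 CPM (-2.72 ± 0.36), with the caveat that near-identical copies can exchange reads. Growth genes fell with them. Of 18 expansins, which loosen cell walls, 10 fell, and 12 adjusted over the list alone (-2.47, 7.91e-05, adjusted p = 0.255 with an estimated correlation), with EXPA5 at -2.25 ± 0.47 and EXPA11 at -3.04 ± 0.65. Of 22 xyloglucan endotransglucosylases, 11 fell and 1 rose by both counts (-2.44, or -2.36 with 2 genes at their bound, 0.000134, adjusted p = 0.261 with an estimated correlation), with XTH7 at -4.01 ± 0.28 and XTH28 at 0.86 ± 0.16. Of 15 cell division genes, 8 fell, and 11 adjusted over the list alone (-2.44, 2.06e-05, adjusted p = 0.271 with an estimated correlation), with CYCB1;2 at -5.46 ± 1.01. Vascular markers had 8 of 10 lower by both counts (-1.75, 2.06e-05, adjusted p = 0.255 with an estimated correlation), with the phloem genes SEOR1 (-2.67 ± 0.32) and SEOR2 (-2.38 ± 0.34). In all, 3035 genes were higher and 3237 lower (48.4% higher, but 63% with total counts alone as library size). With 1 library left out the counts were 1181 and 1330 without GA3 168 h replicate 2. EXPA5 and EXPA11 lost their calls without GA3 168 h replicate 2 (adjusted p up to 0.0574). EXPA11 moved to -4.09 and RBCS2B to -4.92 without GA3 168 h replicate 1, with the call kept. Without GA3 168 h replicate 1 the expansin list's median was -3.7, the cell division list's median was -3.11 and the vascular list's median was -2.39. Without GA3 168 h replicate 2 the xyloglucan endotransglucosylase list's median was -3.66.

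Genes of anthocyanin and glucosinolate synthesis and leaf senescence were among those higher at 168 h of GA3 than in untreated leaves. Anthocyanin synthesis had 7 of 14 genes higher, and 8 adjusted over the list alone (median 2.41, camera adjusted p = 0.000511, adjusted p = 0.347 with an estimated correlation). Its regulator PAP1 stood at 51.3 ± 29.4 against 0.0443 ± 0.0443 CPM, a ratio with a 95% counting interval of 371 to 5270. Glucosinolate synthesis had 8 of 14 higher by both counts (1.51, 0.000399, adjusted p = 0.299 with an estimated correlation), with CYP79F2 (4.1 ± 0.64) and SUR1 (1.43 ± 0.24). Leaf senescence had 7 higher and 1 lower of 13, and 9 and 1 adjusted over the list alone (1.61, 0.00498, adjusted p = 0.417 with an estimated correlation), with the chlorophyll breakdown gene NYE1 (1.81 ± 0.31), NAP (1.75 ± 0.34) and ORE1 (4.11 ± 0.99). The abscisic acid, drought and cold list had 7 of 16 higher, and 7 higher and 1 lower adjusted over the list alone (1.55, 0.0015, adjusted p = 0.347 with an estimated correlation), with HAI2 (5.67 ± 0.87) and P5CS1 (3.45 ± 0.67). Salicylic acid genes had 3 of 18 higher by both counts (1.25, 0.0121, adjusted p = 0.506 with an estimated correlation), with CBP60G at 2.05 ± 0.49, and morning clock genes 5 of 8 by both counts (1.33, 0.00143, adjusted p = 0.278 with an estimated correlation), with LNK1 at 2.47 ± 0.26. The jasmonate list did not pass (0.531, camera adjusted p = 0.119; 2 of 27 higher, 1 adjusted over the list alone), nor did the wound, touch and early pattern-triggered list (0.305, 0.487; 4 higher and 2 lower of 25, 3 and 1 adjusted over the list alone). Floral repressors had 5 of 13 higher, and 6 adjusted over the list alone (0.41, 0.0259, adjusted p = 0.271 with an estimated correlation), with SNZ at 2.36 ± 0.46 and SVP at 1.1 ± 0.25. Of 14 floral promoters, 4 were higher, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0585), with TSF (4.03 ± 0.92) and GI (3.62 ± 0.43). Among other single genes, UMAMIT36 stood at 17.6 ± 7.84 against 0.0295 ± 0.0511 CPM, a ratio with a 95% counting interval of 156 to 4690, and NUDT24 (7.86 ± 1.35), PYD4 (7.74 ± 1.73), GolS2 (7.7 ± 0.98) and LSU1 (7.28 ± 1.01) rose. The repressor call ended without untreated replicate 1 (adjusted p = 0.0576) and GA3 168 h replicate 2 (0.161), and the salicylic acid call without untreated replicate 2 (0.0549) and GA3 168 h replicate 1 (0.0745, median 0.46). SVP, CBP60G, NAP and ORE1 (then at 2.34) lost their calls without GA3 168 h replicate 2 (adjusted p up to 0.148). HAI2 moved to 6.57 without untreated 0 h replicate 1, with the call kept. TSF moved to 4.83 and CYP79F2 to 4.7 without untreated 0 h replicate 2, with the call kept. ORE1 moved to 4.87 without GA3 168 h replicate 1, with the call kept. NUDT24 moved to 7.15 and PYD4 to 7.11 without GA3 168 h replicate 2, with the call kept. Without untreated 0 h replicate 1 the salicylic acid list's median was 2.97. Without GA3 168 h replicate 1 the anthocyanin list's median was 3.1. Without GA3 168 h replicate 2 the anthocyanin list's median was 1.35.

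Gibberellin genes at 168 h of GA3 against untreated leaves included 3 of 8 DELLA targets lower, and 4 adjusted over the list alone (median -0.66, camera adjusted p = 0.0168, adjusted p = 0.261 with an estimated correlation), with BHLH137 (-5.43 ± 0.86) and BHLH154 (-3.91 ± 0.61). The inactivation genes GAMT2 (6.21 ± 1.2) and GA2OX2 (2.56 ± 0.61) rose, 2 of 4 tested by both counts. The GASA family of gibberellin-responsive peptides had 6 of 10 lower and 1 higher by both counts (-2.34, 0.00468, adjusted p = 0.255 with an estimated correlation), with GASA14 (-5.97 ± 0.81) and GASA9 (-3.28 ± 0.64). PRE and auxin-response genes had 3 lower and 1 higher of 20, and 2 and 1 adjusted over the list alone (-1.27, 0.0381, adjusted p = 0.417 with an estimated correlation), with IAA19 at -2.77 ± 0.53 and ATHB2 at 2.78 ± 0.57. Epidermis markers had 5 of 7 lower, and 6 adjusted over the list alone (-1.77, 0.00105, adjusted p = 0.255 with an estimated correlation), with ATML1 at -1.84 ± 0.21. The cytochrome P450 gene CYP78A8 had 0 counts at 168 h against 8.63 ± 1.74 CPM, at least 134-fold lower, and the lipase gene LTL1 0 counts against 100 ± 82.7 CPM, at least 1510-fold lower. The cell wall protein gene CWLP (-7.4 ± 0.88), BZIP61 (-7.4 ± 1.21), SLAH2 (-7.03 ± 0.98) and DGR2 (-7.01 ± 1.03) fell. BZIP61 did not pass under every alternative (adjusted p up to 0.0504 over its alternatives). Gibberellin perception and signalling did not pass as a list (0.13, camera adjusted p = 0.762; 2 higher and 1 lower of 13, 1 and 0 adjusted over the list alone), nor did trichome regulators (0.39, 0.585; 1 of 8 higher, 0 adjusted over the list alone) or guard cell markers (-0.59, 0.663; 1 higher and 1 lower of 5, 1 and 3 adjusted over the list alone). Of the floral organ markers 2 were tested, with 0 called and 1 higher adjusted over the list alone, of the shoot meristem markers CLV1 alone (-0.14 ± 0.26, and 0.01 without GA3 168 h replicate 2), and of the seed markers FUS3 alone (1.47 ± 0.63, higher only when adjusted over the list alone). The DELLA call ended without untreated replicate 1 (adjusted p = 0.0576) and GA3 168 h replicate 1 (0.0566), and the PRE and auxin call without untreated replicate 2 (0.0621) and GA3 168 h replicate 2 (0.092). LTL1 lost its call without GA3 168 h replicate 1 (adjusted p = 0.0544). LTL1 and GA2OX2 (then at 0.78) lost their calls without GA3 168 h replicate 2 (adjusted p up to 0.357). GAMT2 moved to 5.62 without untreated 0 h replicate 1, with the call kept. GAMT2 moved to 9.74 without untreated 0 h replicate 2, with the call kept. CWLP moved to -8.68, BZIP61 to -6.72, SLAH2 to -8.87, DGR2 to -9.47, GA2OX2 to 3.33, GASA14 to -5.14 and ATHB2 to 2.16 without GA3 168 h replicate 1, with the call kept. CWLP moved to -6.79, BZIP61 to -8.73, SLAH2 to -6.3, DGR2 to -6.21, GASA14 to -8.14 and GASA9 to -3.87 without GA3 168 h replicate 2, with the call kept.

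**Figure D2:**
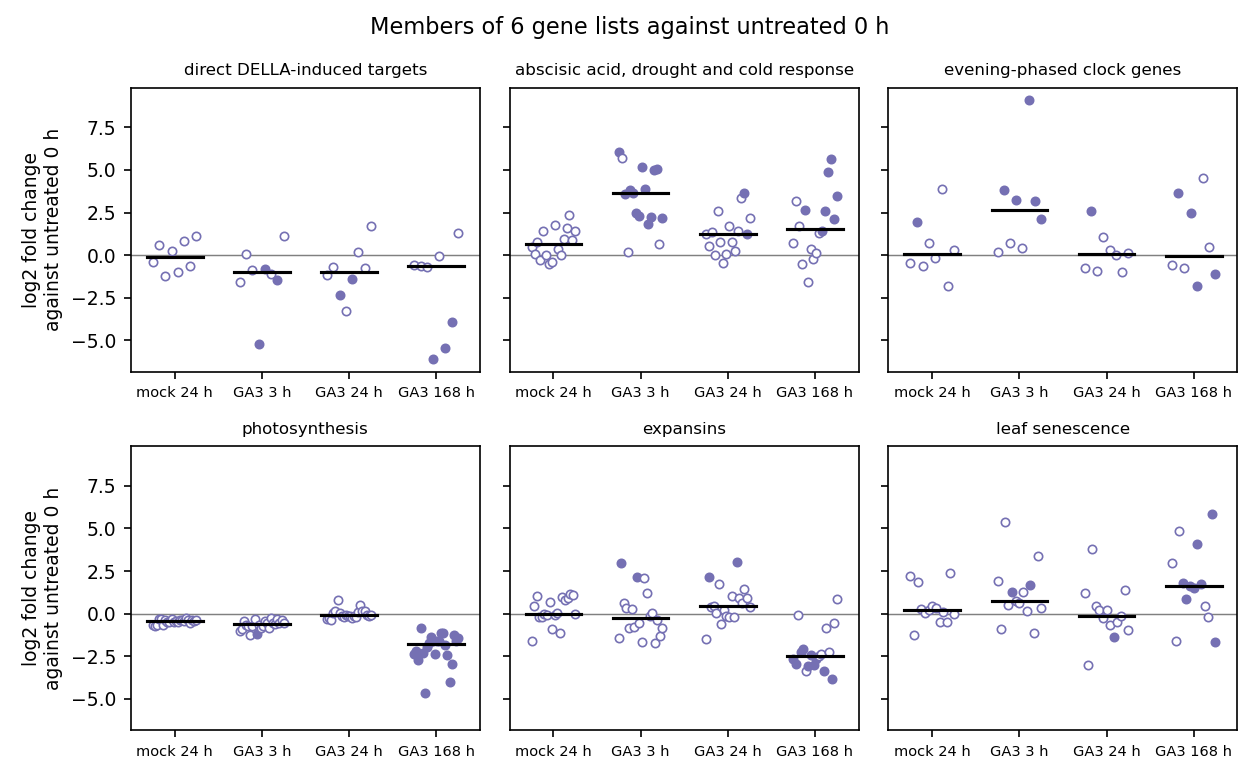
Log2 fold change against untreated leaves at 0 h of every tested member of 6 gene lists, for mock at 24 h and GA3 at 3 h, 24 h and 168 h (filled circles passed an adjusted p of 0.05, open circles did not, black lines are medians). The lists are DELLA-induced targets, abscisic acid with drought and cold, evening clock, photosynthesis, expansins and leaf senescence. The abscisic acid, drought and cold list had its highest median at 3 h (3.62), and photosynthesis its lowest at 168 h (-1.79), where expansins stood lower still (-2.47).

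The comparison of GA3 at 24 h with GA3 at 3 h tested which genes differed between these times. Harvest times are not in the labels, and no mock was taken at 3 h. A fall here can therefore reflect time of day or injection as well as GA3. Evening clock genes fell, 5 of 8 over all genes and 7 adjusted over the list alone (median log2 fold change -1.8, camera adjusted p = 3.19e-07, 0.0389 with an estimated correlation), with GRP7 (-1.98 ± 0.29), PRR5 (-4.17 ± 0.69) and ELF3 (-1.62 ± 0.27). The abscisic acid, drought and cold list fell, 7 of 16 and 8 adjusted over the list alone (-1.95, 3.19e-07, adjusted p = 0.419 with an estimated correlation), with RD29A from 2120 to 74.9 CPM (-4.83 ± 0.46, adjusted p = 0.000372), KIN1 (-3.45 ± 0.52) and ERD10 (-2.23 ± 0.36). The inactivation gene GA2OX6 fell from 56.8 ± 14.5 to 4.81 ± 3.41 CPM (-3.56 ± 0.4), the 1 of 4 by both counts. Gibberellin perception and signalling genes fell, 5 of 13 over all genes, and 6 with 1 higher adjusted over the list alone (-0.55, 0.0159, adjusted p = 0.233 with an estimated correlation), with GID1C at -1.41 ± 0.21. Morning clock genes had 4 higher and 1 lower of 8 by both counts (0.86, 0.00246, adjusted p = 0.616 with an estimated correlation), with LHY at 2.81 ± 0.25. Jasmonate genes had 2 of 27 lower by both counts (-1, 0.00246, adjusted p = 0.642 with an estimated correlation), with JAR1 (-1.68 ± 0.23) and AOC3 (-2.81 ± 0.42). PROPEP3 (-6.68 ± 1.04), ERF53 (-5.91 ± 0.81), WRKY55 (-5.28 ± 0.9) and WRKY30 (-5.17 ± 0.75) were among the falls that also held without each library, and BGLU28, at 5.67 ± 5.48 CPM against 0 counts, was at least 124-fold higher. In all, 1141 genes were higher and 1149 lower, 2290 together (49.8% higher, but 29.2% with total counts alone as library size). With 1 library left out the counts were 900 without GA3 3 h replicate 2, 749 without GA3 24 h replicate 2 and 1440 without GA3 24 h replicate 3. All the genes named here kept the call without each library in turn. BGLU28 did not pass under every other alternative (adjusted p up to 0.107 over its alternatives). PROPEP3 moved to -6.07 and WRKY30 to -4.58 without GA3 3 h replicate 2, with the call kept. KIN1 moved to -2.82 without GA3 3 h replicate 3, with the call kept. PROPEP3 moved to -7.31 without GA3 24 h replicate 1, with the call kept. ERF53 moved to -6.79 and GA2OX6 to -4.32 without GA3 24 h replicate 3, with the call kept. Without GA3 3 h replicate 3 the abscisic acid list's median was -0.7.

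Several lists rose between 3 h and 24 h of GA3. Xyloglucan endotransglucosylases had 2 of 22 higher by both counts (median 1.48, camera adjusted p = 0.00246, adjusted p = 0.616 with an estimated correlation), with XTH7 (1.49 ± 0.21) and XTH9 (2.57 ± 0.59). Glucosinolate synthesis had 5 of 14 higher, and 6 adjusted over the list alone (0.97, 0.00556, adjusted p = 0.642 with an estimated correlation), with SUR1 at 0.92 ± 0.22. The same estimated p of 0.642 belonged to photosynthesis (0.64, 0.00034; LHCB4.2 higher over all genes, 0 adjusted over the list alone), cell division (0.77, 0.00813; CYCA1;1 higher over all genes, 0 adjusted over the list alone) and salicylic acid genes (1.27, 0.0187; WRKY62 at 3.25 ± 0.89 and WRKY38 at 5.31 ± 1.52 by both counts), and to leaf senescence, which was lower (-1.3, 0.0158; 3 of 13 by both counts, with WRKY6 at -2.18 ± 0.34 and NAP at -1.53 ± 0.32). Vascular markers had a median of 0.56 (0.00627, adjusted p = 0.616 with an estimated correlation) with 0 of 10 over all genes in edgeR's test and 5 adjusted over the list alone. Calls of lists that ended with 1 library left out were those of cell division without GA3 3 h replicate 3 (adjusted p = 0.158) and GA3 24 h replicate 3 (0.0612), salicylic acid without GA3 3 h replicate 1 (0.193) and GA3 24 h replicate 1 (0.215, median 0.51), glucosinolate (0.074) and senescence (0.857, median 0.26) without GA3 3 h replicate 3, and vascular without GA3 24 h replicate 3 (0.0612). WRKY38, XTH9 and WRKY62 lost their calls without GA3 3 h replicate 1 (adjusted p up to 0.112). WRKY38, XTH9, CYCA1;1, WRKY62, LHCB4.2 and SUR1 lost their calls without GA3 3 h replicate 2 (adjusted p up to 0.135). WRKY38, CYCA1;1, WRKY62, LHCB4.2 and SUR1 lost their calls without GA3 3 h replicate 3 (adjusted p up to 0.117). WRKY38 (then at 4.71), CYCA1;1, WRKY62 (then at 2.37) and SUR1 lost their calls without GA3 24 h replicate 1 (adjusted p up to 0.104). WRKY38, CYCA1;1, WRKY62, LHCB4.2, SUR1 and NAP lost their calls without GA3 24 h replicate 2 (adjusted p up to 0.128). WRKY38, XTH9 (then at 1.54), CYCA1;1 and LHCB4.2 lost their calls without GA3 24 h replicate 3 (adjusted p up to 0.145). Without GA3 24 h replicate 3 the xyloglucan endotransglucosylase list's median was 0.72.

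The comparison of GA3 at 168 h with GA3 at 24 h placed the late changes after the first day. All 22 photosynthesis genes fell by both counts, over all genes and adjusted over the list alone (median log2 fold change -1.77, camera adjusted p = 1.19e-15, adjusted p = 0.229 with an estimated correlation), with RBCS3B at -3.14 ± 0.35 (adjusted p = 0.000851) and LHCB2.2 at -2.44 ± 0.37. Cell division genes fell, 11 of 15 and 14 adjusted over the list alone (-2.95, 8.04e-09, adjusted p = 0.229 with an estimated correlation), with CDKB2;1 at -3.21 ± 0.56. Vascular markers fell, 8 of 10 by both counts (-2.43, 1.54e-08, adjusted p = 0.202 with an estimated correlation), with XCP1 at -3.75 ± 0.45, and expansins, 11 of 18 by both counts (-2.57, 4.05e-07, adjusted p = 0.202 with an estimated correlation), with EXPA3 at -5.15 ± 0.77. Xyloglucan endotransglucosylases fell, 11 of 22 and 12 adjusted over the list alone (-3.1, 1.51e-06, adjusted p = 0.229 with an estimated correlation), with XTH32 at -3.3 ± 0.53, and so did GASA genes, 6 of 10, and 7 with 1 higher adjusted over the list alone (-2.75, 0.00219, adjusted p = 0.229 with an estimated correlation), with GASA7 at -5.38 ± 0.86. PRE and auxin-response genes had 4 lower and 1 higher of 20 by both counts (-1.02, 0.034, adjusted p = 0.423 with an estimated correlation), with IAA6 at 0.0631 against 13.8 CPM, a ratio with a 95% counting interval of 71.1 to 1010. GASA7 and IAA6 did not pass under every alternative (adjusted p up to 0.108 and 0.0794 over their alternatives). Leaf senescence rose, 6 of 13 and 7 adjusted over the list alone (1.36, 0.000376, adjusted p = 0.4 with an estimated correlation), with NAP at 3.13 ± 0.35, and anthocyanin synthesis, 4 of 14 by both counts (2.78, 0.00219, adjusted p = 0.451 with an estimated correlation), with PAP1 at 4.63 ± 0.94. XERICO rose from 5.62 ± 0.387 to 14.2 ± 2.42 CPM (1.34 ± 0.23), and CYP78A8 had 0 counts at 168 h, at least 131-fold lower. In all, 2067 genes were higher and 2789 lower, 4856 together (42.6% higher, but 64.8% with total counts alone as library size). The PRE and auxin call ended without GA3 24 h replicate 1 (adjusted p = 0.0851) and GA3 168 h replicate 2 (0.0822), and the anthocyanin call without GA3 168 h replicate 2 (0.0822, median 0.89). With 1 library left out the counts were 3082 without GA3 24 h replicate 2, 2650 without GA3 24 h replicate 3 and 898 without GA3 168 h replicate 2. PAP1 (then at 3.84) lost its call without GA3 168 h replicate 2 (adjusted p = 0.0595). EXPA3 moved to -7.6, XTH32 to -4.51, CDKB2;1 to -4.03 and XCP1 to -4.67 without GA3 168 h replicate 1, with the call kept. EXPA3 moved to -4.34 and XTH32 to -2.7 without GA3 168 h replicate 2, with the call kept. Without GA3 24 h replicate 2 the anthocyanin list's median was 3.69. Without GA3 168 h replicate 1 the expansin list's median was -4.03, the PRE and auxin list's median was -1.78, the cell division list's median was -3.83 and the anthocyanin list's median was 3.55. Without GA3 168 h replicate 2 the xyloglucan endotransglucosylase list's median was -4.17.

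**Figure D3:**
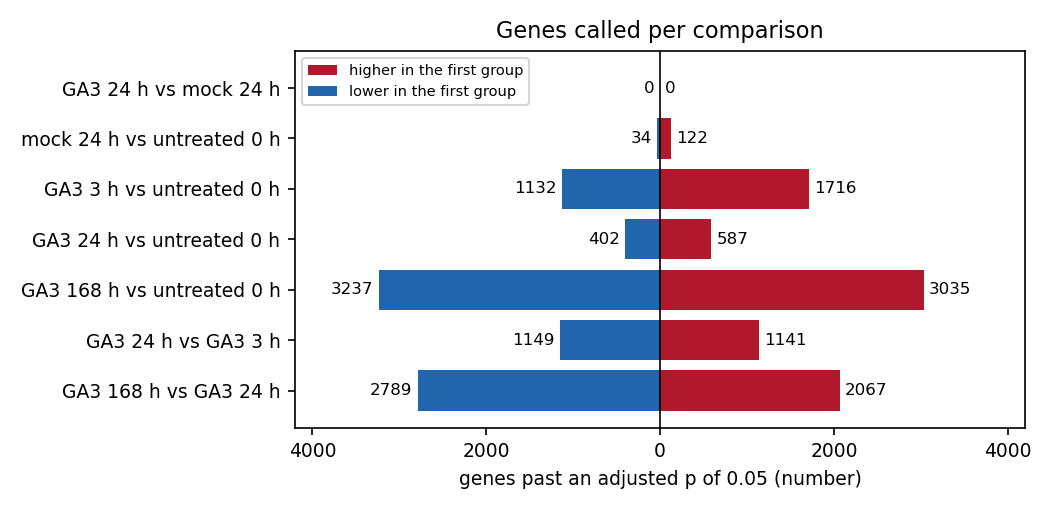
Number of genes past an adjusted p of 0.05 in each of the 7 comparisons, higher in the first group to the right and lower to the left. GA3 at 24 h against mock had 0 in both directions, and GA3 at 168 h against untreated leaves had 3035 and 3237.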

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

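The tests of time of day, injection without GA3, plant age and size factors, and the splits of the DELLA median, were chosen after the result was seen. The change from 0 h differed between 3 h and 24 h of GA3 for 2290 genes and between 24 h and 168 h for 4856 genes in edgeR's quasi-likelihood test of the difference itself. Evening clock genes were among the former, with a median log2 fold change of -1.8. On the strand opposite to the one used for the comparisons, where 10343 genes could be tested, 395 genes differed between 3 h of GA3 and 0 h and 1102 between 168 h and 0 h. At 3 h 157 of them were also called on the main strand in the same direction and 7 in the opposite direction, and at 168 h 551 and 33. Whether these reads are antisense transcripts or strand errors was not analysed here.

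DELLA-induced targets were lower with GA3 than with mock at 24 h (median -0.73) while no gene passed edgeR's test. The low median did not rest on 1 library, since the value nearest to 0 with each library left out was -0.51. The spread between replicates may account for the absence of called genes with changes near 2-fold, as 20% of simulated 2-fold changes were recovered at this size. Of simulated 4-fold changes 68% were recovered, and 96 genes were called in all with 200 changed. That share belongs to a setting with 200 changed genes, and with fewer changed genes the adjustment is stricter. It therefore does not decide whether spread accounts for the lack of calls among larger changes. Fits beyond 4-fold did occur without a call by edgeR, in both directions, such as GA3OX1 (-3.54) and AT2G42900 (3.5). Splits of the 6 libraries cannot test a count of 0, which all 10 reach (highest other 1). A median as large came from 2 of the 10, the real split (-0.73) and a mixed one that was larger in size (0.75). The splits therefore do not set the real grouping apart, and 10 are too few for a share under 0.05.

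The abscisic acid, drought and cold list was higher at 3 h of GA3 than at 0 h (median 3.62). Without GA3 3 h replicate 3 the median was 1.97, so that library might have raised the size, and its part stays open. Time of day could also contribute, since evening clock genes had a median of 2.64 at 3 h, and harvest times are not in the labels. Injection itself stays open as well, with a median of 0.64 for an empty needle at 24 h and no empty needle at 3 h. Of the 10 splits 1, the real one, gave as many called genes (2848, highest other 1), too few splits for a share under 0.05.

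Photosynthesis genes were lower at 168 h of GA3 than at 0 h (median -1.79). The TMM size factors are argued against as the whole cause by the median of -1.6 with total counts alone as library size, and a single library by the median of -1.59 nearest to 0 with each library left out. RNA per leaf was not measured. Plant age could be the cause and stays open, since leaf senescence genes had a median of 1.61 and no plants without GA3 were taken at 168 h. GA3 itself was therefore not tested at that time. Time of day stays open as well, as harvest times are not in the labels.

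In the other comparisons of 3 against 3 the real counts were 156 for mock against 0 h, 989 for 24 h of GA3 against 0 h and 2290 for 24 h against 3 h of GA3, in each of which 1 split was as large and the highest other was 0. The 10 splits are too few for a share under 0.05.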

How the results depend on the processing

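Total counts alone as library size, the counts that ignore strand, robust dispersions, limma-voom with library weights and the fit without the 3 libraries least like their own group (untreated replicate 1, GA3 3 h replicate 3, GA3 24 h replicate 1) were chosen after seeing the data. RLE size factors, organelle genes left out, both filters, unstranded counts and robust dispersions kept every count within 1.5 times. Of 389 named gene results, 384 kept direction and side of the threshold with RLE, 388 without organelle genes, 367 with DESeq2 and 317 with limma-voom. DESeq2 added 10 calls, reversed 1 and gave the others no adjusted p. With only the 2 groups compared, 263 kept both and 123 lost the call. Without the 3 libraries least like their own group, 332 kept both and 53 lost the call. With libraries left out, 1464 values kept both, 690 lost the call, 0 gained one and 5 reversed. DESeq2 gave 19 higher and 30 lower (GA3 against mock), 770 and 351 (mock against 0 h), 1897 lower (3 h), 1464 and 1003 (24 h), and 3710 (24 h against 3 h). Limma-voom gave 30 and 6 for mock against 0 h. Total counts alone gave 11 lower for mock against 0 h and 11 lists for GA3 against mock, and of the named genes 22 lost the call. With only the 2 groups compared there were 752 lower at 3 h, 0 and 0 at 24 h, 2091 lower at 168 h, 1059 for 24 h against 3 h and 2096 for 168 h against 24 h, with fewer libraries to estimate the spread. Library weights gave 1167 and 800 (mock), 3930 and 3520 (3 h), 2264 and 2092 (24 h), and 6509 (24 h against 3 h). Without the 3 libraries there were 740 and 307 (mock), 1785 lower (3 h) and 7 lists for 24 h against 3 h. Lists past the threshold with an estimated correlation were 0 (GA3 against mock), 1 (mock against 0 h), 0 (3 h), 0 (24 h), 0 (168 h), 1 (24 h against 3 h) and 0 (168 h against 24 h). By fry they were 0 (GA3 against mock), 2 (mock), 5 (3 h), 5 (24 h), 16 (168 h), 5 (24 h against 3 h) and 12 (168 h against 24 h). Counts with each library left out in turn ranged from 4 to 179 higher and 0 to 54 lower (mock), 910 to 1721 and 496 to 1304 (3 h), 6 to 802 and 0 to 582 (24 h), and 1181 to 3071 and 1330 to 3271 (168 h). They ranged from 749 to 2128 for 24 h against 3 h, from 898 to 5325 for 168 h against 24 h, and lists from 3 to 12 (GA3 against mock) and 5 to 12 (24 h). GASA6 in GA3 against mock (-0.01) was 0.01 with RLE, 0.01 with DESeq2, 0.21 with limma-voom, 0.22 with library weights, 0.27 without the 3 libraries, and 0.26, 0.25 and 0.29 without GA3 24 h replicate 1, mock replicate 2 and mock replicate 3. GA2OX6 was -0.06 without GA3 24 h replicate 3, and CLV1 at 168 h (-0.14) was 0.01 without GA3 168 h replicate 2 and 0.05 with total counts alone. Over libraries left out, GASA6 ranged from -0.45 to 0.29, GA2OX6 from -0.06 to 0.99 and CLV1 from -0.39 to 0.01. Beyond the fewer libraries, the cause was not tested. At this depth 20% of simulated 2-fold and 68% of simulated 4-fold changes were recovered with 3 libraries against 3.

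With replicate number as a block, counts stayed within 1.5 times, 46 of the 389 named gene results lost the call, 342 kept their side of the threshold, all 65 list calls were kept, and GASA6 stood at 0.05. Of 26 correlations between same-number residuals 10 passed 0.1 (range -0.29 to 0.31), against 12 of 52 between different numbers (-0.33 to 0.33), and 7 of 14 libraries correlated best with their own number. The libraries were not treated as paired, since not every same-number correlation passed 0.1, and partial sharing stays open.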

Other observations

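Both lists described here, low-sulfur response and lignin synthesis, were chosen after the results were seen, as were all their tests. The former was made after ATSDI1, LSU1, LSU2 and BGLU28 had been seen among the largest changes, so its p-values describe genes picked for their rise. Its median lay above 0 in every later group against 0 h. Of 12 tested, 6 were called higher in mock at 24 h (median log2 fold change 2.73, camera p = 3.96e-25, 0.00259 with an estimated correlation) and 10 with GA3 at 24 h (2.92, 1.69e-23, 0.00282 with an estimated correlation). At 3 h of GA3 6 were higher (1.96, 2.37e-06, 0.0849 with an estimated correlation), while SULTR4;2 stood at -0.06 and BGLU28 at 0 against 0.452 CPM, and at 168 h all 12 (3.8, 4.27e-16, 0.00954 with an estimated correlation). Between GA3 and mock at 24 h edgeR's test called 0 (0.44, 0.0291, 0.385 with an estimated correlation).

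The list of lignin synthesis genes, which build a wall polymer, holds PRX52, seen before as one of the largest rises, so the same limit applies to its p-values. Its median lay above 0 after injection with and without GA3, though PAL2 (0.14), CYP98A3 (0.13), HCT (0.08) and MYB58 (-0.14) stood near 0 in mock. Of 19 tested, 7 were called higher in mock at 24 h (0.87, camera p = 1.68e-20, 0.00291 with an estimated correlation), 13 at 3 h of GA3 (1.36, 1.13e-17, 0.00421 with an estimated correlation), 7 at 24 h (0.84, 3.29e-09, 0.0269 with an estimated correlation) and 12 at 168 h (1.04, 3.56e-07, 0.0518 with an estimated correlation). From 3 h to 24 h of GA3 8 fell (-0.64, 7.07e-06, 0.0731 with an estimated correlation). Between GA3 and mock edgeR's test called 0 (-0.35, 7.04e-05, 0.107 with an estimated correlation).

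GA3 3 h replicate 3 had the lowest mean correlation with its own group (0.936) and the highest share of multimapping reads (4.65%), followed by untreated replicate 1 (0.939) and GA3 24 h replicate 1 (0.947).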
